A study of Homo sapiens with 12 samples.

How the data were processed

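HEK293T cells carrying shNS, shMETTL16-1 or shMETTL16-2 were selected with 2 µg/ml puromycin, per the labels' protocols. Input and m6A IP libraries were made from nascent RNA (400 µM 4-thiouridine for 1 h) and from nuclear poly(A) RNA, 12 libraries in 12 groups of 1. The 2 hairpins stand for separate knockdowns and are not replicates, and both are compared with the same shNS libraries. No paired or blocked analysis was made, because no group has a second library.

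Reads were aligned with STAR to GRCh38, per the submitters' processing notes, with no version given. The peak caller and its settings are not given in the sources used here. The authors deposited 4 tables of intervals, 1 per METTL16 hairpin and RNA population. Per the file headers, each interval has a score, which equals its p-value, and the log10 of its p-value and FDR as the authors deposited them. The deposited fold enrichment is a ratio of IP over input. The deposited differential columns hold a log10 p-value, a log10 FDR and a log2 fold change between the 2 conditions. The authors' tables give values per comparison and not per library, so no read totals, abundances or replicate errors can be computed, and the knockdown of METTL16 could not be checked. The score and the log10 p-value differed by at most 0.02 log10 units, from rounding. The number of value columns belonging to other samples is 0. Every interval is a single block from start to end. Between 448 and 1360 rows per table share their place with another gene name, and such genes are uncertain.

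Starts were raised by 1 to give 1-based GRCh38 coordinates. Gene names were brought up to date through a RefSeq gene table of GRCh38.p14. Of 13476, 26609, 14550 and 14734 names in the nascent shMETTL16-1, nascent shMETTL16-2, nuclear shMETTL16-1 and nuclear shMETTL16-2 tables, 12333, 23776, 13276 and 13447 were current and 754, 1393, 827 and 831 matched an older name. The others were kept as listed. No genome sequence was used, so the planned count of METTL16 target motifs and of peaks per transcript part was not run.

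The main counts are peaks at the authors' differential FDR under 0.05, by the sign of the deposited log2 value. Their test compares the reads of single libraries. Peaks of 2 tables were matched with bedtools 2.31.1 on the same strand where the overlap covered at least 50% of the shorter peak. Correlations used, for each peak, the partner of the same gene with the largest overlap. The overlap of independent lists was counted in matched peaks of the first table. It is the number of them called, times the number that overlap a call of the second table, over the number matched. The first table is the shMETTL16-1 one or, between RNA populations, the nascent one for shMETTL16-1 and the nuclear one for shMETTL16-2. A wide call of the second table counts once for each peak it overlaps. A gene's value for the lists is the median log2 value of its peaks, and a list's median was ranked among 10000 random lists of the same size matched on fold enrichment decile, as a description without a p-value. Ties in fold enrichment were split by gene name. This matching was thus weak in the nascent shMETTL16-2 table, where 215171 of 279549 rows had a fold enrichment of 1.00. Counts of list members are out of those in the shMETTL16-1 table of the RNA population. The 17 lists, the thresholds, the matching rule and the alternatives were set before the data were examined, except where stated.

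The genes named are METTL16, MAT2A, MALAT1 and U6. To these the rule adds, per RNA population, the 10 most changed genes lower with both hairpins by the smaller absolute log2 value at a fold enrichment of at least 2. It adds in the same way those higher with both, of which there were none. It adds from each list up to 4 members called with both hairpins, of which the text gives some; 1 member of the histone list is not reported here. ROBO2, GULP1, DIAPH2 and the genes of the higher calls were named after their values were seen.

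To find what the differential columns hold, every set of 4 whole counts with a sum of at most 30 was turned into a log2 ratio of ratios and a hypergeometric log10 p-value. Deposited pairs were looked up among them at 3 significant digits. Such a pair cannot always be assigned to libraries, since exchanging the shNS input with the knockdown IP leaves it the same. A separate look-up took the knockdown IP and input as 1 repeated count, with up to 60 shNS IP, 4 shNS input and 40 repeated reads, and kept pairs with a single reading. It gave the repeated counts set against the shNS counts, with bootstrap limits from resampled peaks, and the shNS counts for the simulation below. The same look-up with up to 40 shNS input reads was used for narrow peaks. Of the readings, the fold enrichment of narrow peaks followed the one with a repeated count in IP and input (r between 0.832 and 0.870) more closely than the one with it in both inputs (r between 0.533 and 0.648). The look-up was tested on 20000 simulated peaks and held the true counts among its readings for 99.9% of them where IP and input were equal. Matching and list ranking were tested on simulated data with known answers. Unchanged hairpins were simulated with 20 Poisson draws around the shNS counts read back, with the shNS draw shared by both hairpins.

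Alternatives were an FDR under 0.01, a log2 value of at least 1, a fold enrichment of at least 2, centring on the median, 1 value per gene, overlaps of 1 base and of 80%, and 2 for the lists. Limiting the nascent shMETTL16-2 table to a fold enrichment above 1, or the nascent intervals to under 1000 bp, was chosen after seeing the data. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.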

Results

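N6-methyladenosine (m6A), a methyl mark on adenosines of RNA, was mapped by MeRIP-seq, in which fragments bound by an m6A antibody (IP) are sequenced beside the unselected fragments (input). The cells were HEK293T, a human embryonic kidney line that carries the SV40 large T antigen. They carried a control hairpin (shNS) or 1 of 2 hairpins against METTL16, a methyltransferase known to act on MAT2A mRNA and the U6 small nuclear RNA. For each hairpin, input and IP were made from nascent RNA, labelled with 400 µM 4-thiouridine for 1 h, and from nuclear poly(A) RNA. The 12 groups held 1 library each, so no difference below has a replicate check, and every test compares libraries, not conditions.

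The authors' tables set each METTL16 hairpin against shNS within an RNA population. In nascent RNA 62265 intervals in 13468 genes were listed with shMETTL16-1 and 279549 intervals in 26569 genes with shMETTL16-2. In nuclear poly(A) RNA the tables listed 57438 and 59670 intervals in 14536 and 14720 genes. With a peak FDR under 0.05 there were 7593 and 6616 peaks in nascent RNA and 9377 and 9158 in nuclear poly(A) RNA. The median fold enrichment of such peaks lay between 10.8 and 11 in all 4 tables. Read totals per library are not known from these tables, so the depth behind a peak is unknown except where its small counts could be read back.

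The deposited differential log2 value, knockdown over shNS, was the same for both hairpins at shared places in nuclear poly(A) RNA. Both nuclear tables listed 38463 peaks of the same gene with the same coordinates, and the log2 value was identical at 38463 of them, including the METTL16, MAT2A and MALAT1 peaks. The differential p-value was the same at 51.1% of them, and at 8.50% of the 3058 called with both hairpins, so reads of the hairpin enter the p-value but cancel from the log2 value at called peaks too. In rows of low coverage the log2 value and p-value could be read back as 4 whole counts with a sum of at most 30. Of the rows read with at least 4 knockdown reads, equal knockdown IP and input counts were possible for 97.9% with shMETTL16-1 and 98.2% with shMETTL16-2. The share was 95.9% in the nascent shMETTL16-1 table and 25.9% in the nascent shMETTL16-2 table. Simulated counts gave 100% where IP and input were made equal and 38% where they were independent. Where the knockdown counts are equal, the log2 value is the shNS input count over the shNS IP count and holds no knockdown reads. So "lower" below is the sign of the deposited value, and at the shared nuclear places it is no effect of a hairpin. Over all rows read from the nuclear tables, at shared places or not, equal knockdown counts were possible for 99.6% and 99.7%. In the nascent shMETTL16-1 table it was 99.8%, but in the nascent shMETTL16-2 table it was also 82.0%. Simulated independent counts gave 44% over all rows, so this share separates the tables less well. With at least 4 knockdown reads the nascent shares were 95.9% against 25.9%, as above. So in the nascent shMETTL16-1 rows read, too, the value cannot be taken as an effect of a hairpin. What it measures in unread rows away from the shared nuclear places, and in the nascent shMETTL16-2 table, stays open.

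**Figure D1:**
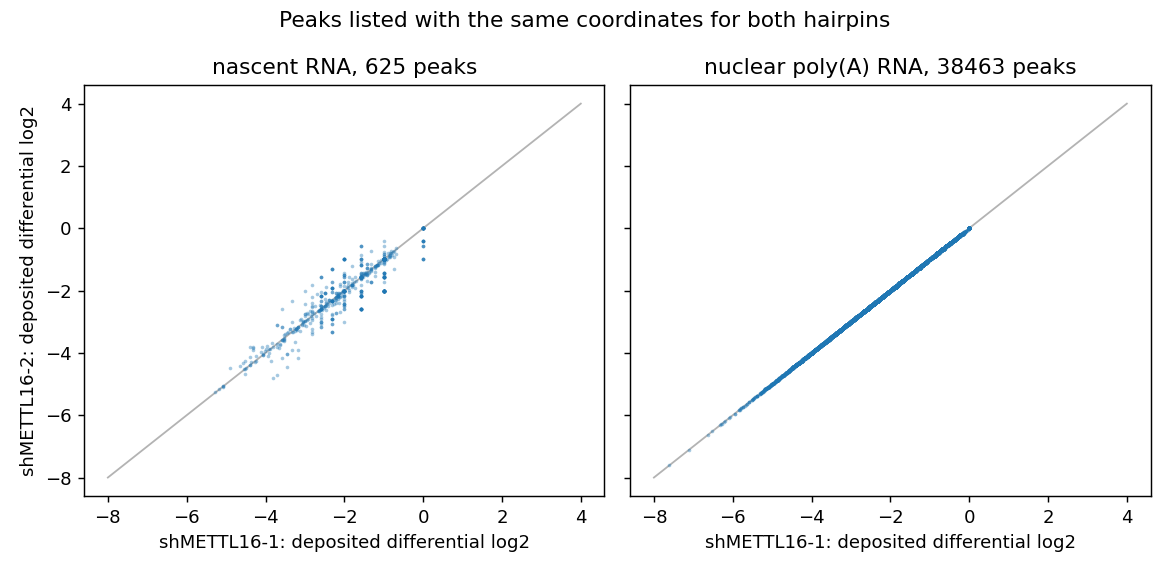
Differential log2 values deposited for shMETTL16-2 (vertical axis) against those for shMETTL16-1 (horizontal axis) at peaks listed with the same coordinates for both hairpins, 1 point per peak, in nascent RNA (left, 625 peaks) and nuclear poly(A) RNA (right, 38463 peaks). All nuclear points lie on the grey line of equal values, and the nascent points scatter around it with an SD of the difference of 0.42. At the 83 nascent peaks called with both hairpins this SD was 0.13.

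The first comparison was that of nascent RNA with shMETTL16-1 against shNS. Equal knockdown IP and input counts were possible for 95.9% of the rows read there with at least 4 knockdown reads. Of its 2954 lower calls, 999 were among the peaks read with 1 repeated knockdown count. What the value measures at the other calls stays open. The lower calls can thus not be taken as an effect of the hairpin. METTL16 itself, MAT2A (the enzyme that makes S-adenosylmethionine) and the long noncoding RNA MALAT1 each held peaks called lower. The METTL16 peak on chromosome 17, 2419383 to 2420583 (GRCh38, minus strand), had a fold enrichment of 35.9, a log2 value of -4.36 and a differential FDR of 3.2e-05 in the authors' deposited table. For MAT2A (chromosome 2, 85544503 to 85545280, plus strand) the authors' deposited table gave a log2 value of -2.51 with a differential FDR of 6.9e-06. MALAT1 (chromosome 11, 65500009 to 65500729, plus strand) stood at -3.63, with a differential FDR of 7.9e-29, in the authors' deposited table. Of all listed peaks of these genes, 1 of 9 in METTL16, 1 of 2 in MAT2A and 2 of 3 in MALAT1 were called. U6 genes were not analysed in this table. In all, 2954 peaks in 2311 genes were called lower and 0 higher at a differential FDR under 0.05, by the authors' test. At an unadjusted p under 0.05 the counts were 4575 and 0, since no row had a log2 value above 0.

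With shMETTL16-2 in nascent RNA the same genes held intervals called lower. These were 1 of 36 listed in METTL16, 1 of 5 in MAT2A and 2 of 8 in MALAT1. Uncalled METTL16 intervals reached a log2 value of 2.35 in the authors' deposited table. The authors' deposited table gave METTL16 a log2 value of -4.10 over an interval of 13647 bp (chromosome 17, 2419203 to 2432849) with a differential FDR of 3.9e-10. MAT2A had -2.55 over the same coordinates as with the other hairpin, and MALAT1 -3.37 (chromosome 11, 65500009 to 65500878), in the authors' deposited table. The 5 U6 genes listed (RNU6-1, RNU6-2, RNU6-7, RNU6-8 and RNU6-9) had a fold enrichment of 1.00 and a log2 value of 0.00 in the authors' deposited table. These are near-identical copies listed over 2 shared places, so their reads could not be assigned. In all, 5436 peaks in 4253 genes were called lower and 119 intervals in 109 genes higher. ROBO2, an axon guidance receptor, had the lowest differential FDR of the higher calls, with a log2 value of 4.55 in the authors' deposited table, over 75748 bp of chromosome 3 (77109861 to 77185608). GULP1, an adaptor for engulfment of dying cells, had 4.66 over 130469 bp and the formin gene DIAPH2 4.80, the highest of the table, over 122158 bp in the authors' deposited table. The higher intervals had a median width of 79739 bp, and 86 of the 119 had a fold enrichment of 1.00. Among intervals under 1000 bp, an alternative chosen after the data were seen, 690 were called lower and 0 higher.

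Among the 10 genes most strongly lower with both hairpins in nascent RNA, STK35, a kinase, had log2 values of -6.61 and -6.79 with shMETTL16-1 and shMETTL16-2 in the authors' deposited tables (chromosome 20, 2116729 to 2117509 with shMETTL16-1). THAP7, a zinc-coordinating transcriptional regulator, had -6.32 and -6.91, and EP300, a histone acetyltransferase, -6.36 and -6.16, in the authors' deposited tables. SLX4, a nuclease scaffold of DNA repair, had -6.02 and -6.63, SEC62, a translocation factor of the endoplasmic reticulum, -6.09 and -6.01, and the small GTPase ARF6 -6.08 and -6.01 in the authors' deposited tables. The others of these 10 in the authors' deposited tables were the autophagy regulator AMBRA1 at -6.00 and -6.58, FAM171B at -5.98 and -6.85, NCBP2AS2 at -6.44 and -5.94 and the Notch target HEY1 at -5.93 and -5.89. Of the 2954 peaks called lower with shMETTL16-1, 2839 in 2226 genes overlapped a lower call of shMETTL16-2 and 0 overlapped a higher one. No peak could be called higher with both, since the shMETTL16-1 table has no log2 value above 0. Independent lists would share 669, counted from the 14094 shMETTL16-1 peaks that overlap a lower call of shMETTL16-2. Every one of the 62265 intervals found a partner among the 279549, and with an overlap of 80% of both peaks the shared lower calls were 559.

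Across those 62265 pairs in nascent RNA, Pearson's r of the log2 values was 0.517, Spearman's rho 0.504 and the covariance 0.982. Peaks are not independent replicates, so no p-value is given. At the 58201 pairs whose counts could be read back, r was 0.474 and the covariance 0.840. Unchanged hairpins simulated against the shared shNS libraries at these peaks gave an r of 0.50 and a covariance of 0.814. These peaks were read with 1 repeated knockdown count for shMETTL16-1, whereas the simulation drew separate hairpin counts. It is thus no measure of chance for the observed r or covariance. The simulation made 0 lower calls for a single hairpin, so it gives no number for shared calls by chance. Where the shMETTL16-1 counts are equal, its log2 value holds shNS reads only, and both hairpins share the shNS libraries. The overlap of lower calls, also beyond that of independent lists, can thus not be taken as agreement of the hairpins. How much of it comes from the shared shNS libraries cannot be split.

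In nuclear poly(A) RNA the peaks of METTL16, MAT2A and MALAT1 were again called lower, with the same log2 value for each hairpin. The METTL16 peak (chromosome 17, 2419833 to 2420553) had a log2 value of -4.58 in both of the authors' deposited tables, with differential FDRs of 1.5e-05 and 4.0e-06 for shMETTL16-1 and shMETTL16-2. Its fold enrichment was 85.1 and 55.8 in the authors' deposited tables. MAT2A (chromosome 2, 85544981 to 85545250) had -2.0 and MALAT1 (chromosome 11, 65500129 to 65500848) -2.17 in both of the authors' deposited tables. Of the listed peaks 1 of 4 in METTL16, 1 of 3 in MAT2A and 1 of 2 in MALAT1 were called with either hairpin. U6 genes were not analysed there. With shMETTL16-1, 4091 peaks in 3121 genes were called lower and 0 higher by the authors' test. With shMETTL16-2, 4592 peaks in 3414 genes were called lower and 0 higher. At an unadjusted p under 0.05 there were 6354 and 6996 lower and 0 higher in either table. Centring each table on its median log2 value (-1.32 and -1.17) left 38 and 28 calls above the median.

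The nuclear peaks called lower with both hairpins were led by B3GALT6, a galactosyltransferase of proteoglycan synthesis, at -7.61 and GAS1, a Hedgehog co-receptor, at -7.11, each the same in both of the authors' deposited tables. USP32, a deubiquitinase, had -6.64, DHRS11, a dehydrogenase, -6.21, GPATCH2 -6.19 and SAC3D1 -6.09 in both of the authors' deposited tables. RNF217 and its antisense partner RNF217-AS1 had -6.52 and -6.32 in both of the authors' deposited tables over overlapping places on opposite strands (chromosome 6, from 124962695 and 124962697), so either value is uncertain. IER5L, an immediate early response gene, had -6.75 and -6.39 and the phosphodiesterase PDE7A -6.09 and -6.11 in the authors' deposited tables, where the hairpins' peaks differ in extent. Of the 4091 lower calls with shMETTL16-1, 3699 in 2851 genes were lower with shMETTL16-2 too, beside 377 for independent lists. Because shared places hold the same log2 value, this overlap does not measure agreement of the hairpins. Neither nuclear table has a log2 value above 0, so higher or opposite calls were not possible.

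Over 51430 matched nuclear pairs r was 0.971, rho 0.970 and the covariance 1.25, and 88.6% of pairs had the same log2 value. At the 41168 pairs read back as counts, r was 0.961 and the covariance 1.15. Unchanged hairpins that share the shNS libraries gave a simulated r of 0.499 and a covariance of 0.884, and again 0 lower calls for a single hairpin. Since the log2 value is the same at all shared places, neither the observed r nor the covariance measures agreement of the hairpins, and this simulation, with separate hairpin counts, is no measure of chance for them.

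Nascent and nuclear poly(A) RNA share no library, and METTL16, MAT2A and MALAT1 were called lower in both. Where the knockdown counts are equal, the log2 value holds shNS reads only. Agreement of the populations can thus not be told apart from agreement of their shNS libraries. With shMETTL16-1, 23137 nascent peaks overlapped a nuclear one. Of these, 1520 in 1310 genes were called lower in both populations, beside 621 for independent lists. Pearson's r of the log2 values was 0.322 and rho 0.323. Neither table has a log2 value above 0, so no pair could have opposite signs. With shMETTL16-2, 56096 nuclear peaks overlapped a nascent interval, and 2814 were lower in both, beside 1091 for independent lists. There r and rho were both 0.392. With an overlap of 80% of both peaks r was 0.676 over 3463 pairs and 0.581 over 461.

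Over all genes listed with shMETTL16-1, 2311 of 13468 in nascent and 3121 of 14536 in nuclear RNA had a lower call. With both hairpins it was 2226 and 2851 genes. Lists with shares near these, such as the cell cycle genes below, do not stand out. Among the gene lists, C2H2 zinc finger factors, whose coding sequence lies mostly in 1 long exon, differed most in their counts between the RNA populations. In nascent RNA 51 of 69 listed members had a lower call with shMETTL16-1 and 50 with both hairpins. In nuclear poly(A) RNA the counts were 17 of 69 and 16. Their nascent medians stood at percentiles 49.4 and 50.8 of random lists, but at 0.49 and 0.00 with a gene's most enriched peak and at 0.00 and 0.06 with lists matched on the number of peaks. ZNF703 (-5.51 and -5.13), ZNF121 (-5.03 with each hairpin), ZNF131 (-4.95 and -5.37) and ZNF281 (-4.83 and -4.84) led in nascent RNA in the authors' deposited tables. In nuclear RNA ZNF711 (-4.17), ZNF703 (-3.86), ZNF121 (-3.77) and ZNF592 (-3.75) led, with 1 value for both hairpins in the authors' deposited tables. Histone genes of the replication-dependent list had a lower call in 13 of 35 members in nascent RNA, 12 with both hairpins, and in 1 of 26 in nuclear poly(A) RNA. Their mRNAs end in a stem-loop and mostly lack a poly(A) tail. H3C2 (-2.74 and -2.76), H4C5 (-2.48 and -2.49) and H3C13 (-2.54 and -2.50) were among those lower with both hairpins in nascent RNA in the authors' deposited tables, and near-identical copies make histone values uncertain. DNA damage and repair genes had 12 of 25 members lower in nascent RNA, 11 with both hairpins, and 4 of 27 in nuclear RNA. BRCA2 (-4.52 and -4.68) led in nascent RNA, and MDM4 had -4.35 and -4.34 in nascent and -4.47 in nuclear RNA in the authors' deposited tables. The difference between RNA populations was not tested for any list, with 1 library per condition.

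**Figure D2:**
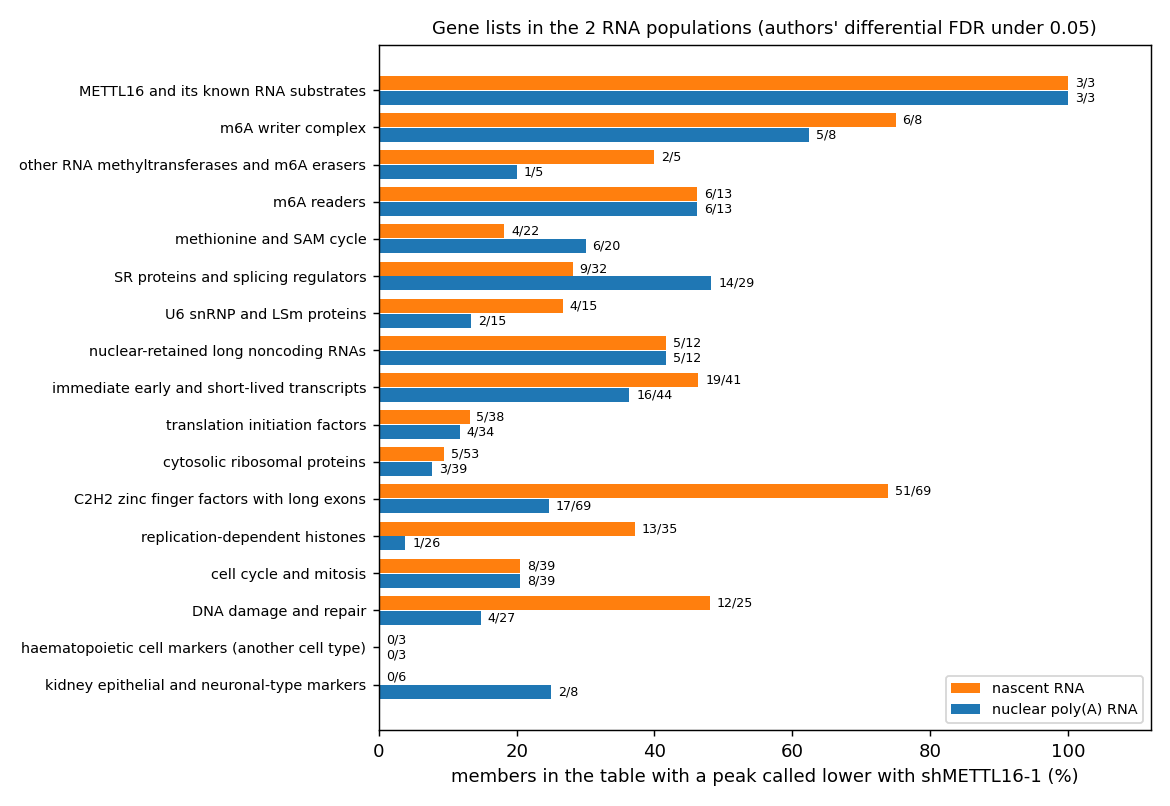
Share of the members listed in a table that had at least 1 peak called lower with shMETTL16-1 (horizontal axis, percent; the numbers beside the bars are counts), for the 17 gene lists (vertical axis) in nascent (orange) and nuclear poly(A) RNA (blue). The zinc finger factors stand at 51 of 69 in nascent and 17 of 69 in nuclear RNA, and the histones at 13 of 35 and 1 of 26. All listed genes stand at 2311 of 13468 and 3121 of 14536.

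Writer complex genes were lower with both hairpins in 6 of 8 members in nascent and 5 of 8 in nuclear RNA. WTAP had -5.16 and -5.18, RBM15B -4.95 and -4.93, RBM15 -4.86 and -4.85 and ZC3H13 -5.22 and -4.16 in nascent RNA in the authors' deposited tables. In nuclear RNA the authors' deposited tables gave ZC3H13 -3.81, RBM15 -3.59, RBM15B -3.52 and WTAP -2.99. Of the m6A readers, 6 of 13 were lower with both hairpins in each RNA population. YTHDF2 had -5.14 and -5.12 in nascent and -3.58 in nuclear RNA, and YTHDF3 -4.77 and -4.83 against -3.46, in the authors' deposited tables. Of the other methyltransferases and erasers, ALKBH5 (-3.77 and -3.64) and FTO (-5.70 over 631 bp and -1.77 over 72748 bp) were lower in nascent and ALKBH5 (-2.49) in nuclear RNA in the authors' deposited tables, which is 2 and 1 of 5 members. Of METTL16 and its known RNA substrates, METTL16, MAT2A and MALAT1 were lower with both hairpins in both populations, and the 5 U6 genes listed with shMETTL16-2 in nascent RNA were not called.

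Short-lived transcripts were lower with both hairpins in 19 of 41 members in nascent and 16 of 44 in nuclear RNA. JUN, an immediate early transcription factor, had -5.72 with each hairpin in nascent RNA, with a differential FDR of 1.0e-110 for shMETTL16-1 in the authors' deposited tables. BTG1 had -4.92 and -4.93 there, and BHLHE40 -5.13 and IER3 -4.77 in nuclear RNA, in the authors' deposited tables. Splicing regulators were lower with both hairpins in 9 of 32 members in nascent and 13 of 29 in nuclear RNA. SON had -4.24 with each hairpin in nascent and -3.45 in nuclear RNA, and U2AF2 -5.18 and -4.96 against -3.57, in the authors' deposited tables. The list of long noncoding RNAs had 5 of 12 members lower with both hairpins in each population. NORAD, which is known mainly from the cytoplasm although the list was drawn up for nuclear-retained RNAs, had -4.44 and -4.38 in nascent and -4.28 in nuclear RNA in the authors' deposited tables, and TUG1 -3.84 and -3.90 against -3.57. Methionine cycle genes were lower with both hairpins in 4 of 22 members in nascent and 6 of 20 in nuclear RNA. The amino acid transporter gene SLC7A5 had -4.38 and -4.02 in nascent and -4.82 in nuclear RNA in the authors' deposited tables.

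U6 snRNP and LSm genes were lower with both hairpins in 4 of 15 members in nascent and 2 of 15 in nuclear RNA, with PRPF4 at -5.25 and -4.38 and SART3 at -3.07 in the authors' deposited tables. Translation initiation factors had 5 of 38 and 3 of 34, led by EIF3A at -4.65 and -4.41 in nascent and EIF4G1 at -4.51 in nuclear RNA in the authors' deposited tables. Ribosomal protein genes had 5 of 53 and 3 of 39, with RPL13A at -2.62 and -2.66 in nascent and -1.79 in nuclear RNA in the authors' deposited tables. The nuclear RPL36 peak (-1.06 in both of the authors' deposited tables) was called lower but lay above its table's median log2 value. Cell cycle genes had 8 of 39 in each population, led by MKI67 (-4.34 and -4.01) in nascent and E2F3 (-4.24) in nuclear RNA in the authors' deposited tables. Haematopoietic markers had 0 of 3 lower with both hairpins in each population. Kidney and neuronal-type markers had 0 of 6 in nascent and 2 of 8 in nuclear RNA, the neurofilament genes NEFL (-2.39) and NEFM (-1.82) in the authors' deposited tables. Of 68 medians (17 lists in 4 tables), 11 lay below the 2.5 or above the 97.5 percentile of 10000 random lists matched on fold enrichment decile. Only 1 of these 11 stayed outside under both list alternatives, that of short-lived transcripts with shMETTL16-2 in nascent RNA, at 0.00 in each. Ties made the matching on fold enrichment weak in that table. Percentiles near 50 there go with list medians at or near 0.00, where ties are many, and do not show that a list is unshifted. With lists matched on the number of peaks, short-lived transcripts stood at 0.01 with shMETTL16-1 in each RNA population. With shMETTL16-2 in nuclear RNA they stood at 0.07. The main percentiles in these tables were 7.67 (nascent shMETTL16-1), 19.98 (nuclear shMETTL16-1) and 2.68 (nuclear shMETTL16-2). With a gene's most enriched peak they lay between 13.2 and 41.8. Only the matching on the number of peaks put short-lived transcripts outside the limits there. The ribosomal protein median stood at 0.12 and 0.00 in the nascent tables, and at 13.8 and 6.40 with lists matched on the number of peaks. With a gene's most enriched peak it stood at 89.1 and 69.1. Also outside were the nuclear shMETTL16-2 medians of ribosomal proteins (98.15) and methionine cycle genes (1.98) and the nascent shMETTL16-1 median of other methyltransferases and erasers (0.35). In this order they stood at 99.7, 29.35 and 39.98 with a gene's most enriched peak. With lists matched on the number of peaks they stood at 97.28, 54.5 and 5.58. The histone median stood at percentile 0.00 in both nascent tables. That of splicing regulators stood at 0.04 in the nascent shMETTL16-1 table, but at 34.5 with random lists matched on the number of peaks per gene and at 50 in the nascent shMETTL16-2 table. In the nuclear tables it stood at 99.5 and 98.2, and at 94.8 and 84.3 with a gene's most enriched peak. With lists matched on the number of peaks the nuclear percentiles were 99.95 and 99.91. With a gene's most enriched peak as its value the nascent histone percentile was 90.0 with shMETTL16-1 and 76.1 with shMETTL16-2. With lists matched on the number of peaks it was 0.07 and 0.00.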

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

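Of 80 alternatives to the planned results, 20 were counts of higher peaks fixed at 0, because a table that enters them has no log2 value above 0. Of the other 60, 34 kept a count within 1.5 times or a correlation within its bootstrap interval and 26 did not. Only a correlation could turn its direction, since counts were not scored for it, and 0 did. All of them are limited by 1 library per condition. The motif analysis was not run, and limiting intervals by width or to a fold enrichment above 1 was chosen after seeing the data. At an FDR under 0.01 the lower calls were 1941 for nascent shMETTL16-1 and 1891 for both nascent hairpins, and the higher calls of nascent shMETTL16-2 were 28, as a stricter threshold calls fewer. For the higher calls of nascent shMETTL16-2, a fold enrichment of at least 2 or above 1 left 33, and intervals under 1000 bp left 0. With such intervals 690 were lower for nascent shMETTL16-2 and 413 for both nascent hairpins, and with an 80% overlap 559 for both. Centring on the median made 38 calls of nuclear shMETTL16-1, 28 of nuclear shMETTL16-2 and 19 of both nuclear hairpins higher, and turned the RPL36 peaks to 0.26 and 0.11. Correlations of the hairpins moved in nascent RNA to 0.936 (80% overlap), 0.485 (fold enrichment of at least 2), 0.206 (1 value per gene) and 0.637 (under 1000 bp), and in nuclear RNA to 0.999, 0.974 and 0.828 under the first 3 of these. Correlations of nascent with nuclear RNA moved to 0.676, 0.253 and 0.305 with shMETTL16-1 and to 0.581, 0.272 and 0.217 with shMETTL16-2. The cause of these moves was not tested. List medians outside the 2.5 to 97.5 percentiles numbered 21 with a gene's most enriched peak, beside 11. Over both list alternatives 92 of 136 list values stayed on their side of these limits, 15 moved inside, 29 moved outside and 0 changed side. Of 252 named peaks 222 kept an FDR under 0.01.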

Other observations

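Peaks were counted along their genes after the data were seen. Of 6242 nascent peaks of the shMETTL16-1 table (peak FDR under 0.05, fold enrichment of at least 2, under 1000 bp, centre inside the named gene), 13.5% lay within 1000 bp of the 3′ end of the gene, with an exact 95% binomial interval of 12.7% to 14.4%. In the nuclear poly(A) shMETTL16-1 table it was 18% of 8471 (17.2% to 18.8%). In the nascent shMETTL16-2 table it was 22.3% of 1460 (20.1% to 24.5%), so the order of nascent and nuclear RNA depends on the table. The limits kept 1508 of the 6616 peaks there, against 6403 of 7593 in the nascent shMETTL16-1 table. Its shares are thus those of a small, narrow part of its peaks. Within 1000 bp of the 5′ end lay 10.9% (10.1% to 11.7%), 10.0% (9.38% to 10.7%) and 17.3% (15.4% to 19.3%) in these 3 tables. The intervals cover counting error only, and gene ends are those of RefSeq. Peaks at a peak FDR under 0.05 with shMETTL16-1 named 4644 genes in nascent and 5907 in nuclear RNA, of which 3495 were in both.

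All tests below were chosen after the result was seen. The log2 values of both hairpins were identical at shared coordinates in nuclear poly(A) RNA. A loss of m6A with either hairpin would bring knockdown IP and input counts close together but leave sampling differences, and equal counts were possible for 97.9% of readable peaks with at least 4 knockdown reads, above the 38% of independent counts, which argues against loss alone as the source. Having 1 hairpin count enter in 2 of the 4 places may account for the identity: a repeated count could be read at these 97.9%, where independent counts would have given fewer. This is the same share as above and no separate test. At the 3058 shared peaks called with both hairpins the log2 value was also the same, while the differential p-value was the same at 8.50%, so hairpin reads cancel from the log2 value there too. Whether METTL16 knockdown changed m6A stays open.

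Only the nascent shMETTL16-2 table held higher calls. A gain of m6A at narrow peaks would need higher calls in intervals under 1000 bp with a fold enrichment of at least 2, and there were 0. Only 473 of the 21310 such intervals had a log2 value above 0. The median width of peaks at a peak FDR under 0.05 in this table was 1980 bp. The 0 calls thus do not decide on a gain at its usual peaks. Whether the higher calls come from intervals kept without enrichment stays open. Of the 119, 72.3% had a fold enrichment of 1.00, but so had 77.0% of all intervals of the table, and the other 33 had more. All 119 were wider than 10000 bp, as were 8.06% of all intervals. Equal counts were possible in 41.6% of readable intervals under 200 bp with at least 4 knockdown reads of this table and in 22.2% of those of 5000 bp or more, so width alone does not account for the difference from the other tables.

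The repeated count of the nuclear tables was set against the shNS counts. From peaks with 5 to 9 to peaks with 20 to 60 shNS IP reads, the shNS IP count rose by a factor between 4.29 and 4.58, and an IP with enrichment like that of shNS would rise with it. At 1 to 4 shNS input reads the mean repeated count rose by a factor between 1.11 and 1.82, with an upper bootstrap limit of at most 1.97, which argues against such an IP. At 1 shNS input read 68.8% and 61.6% of the repeated counts at 5 to 9 shNS IP reads were 1, the lowest possible, which limits the comparison there, but at 4 shNS input reads, with 20.1% and 18.7%, the factors were 1.11 and 1.25. Whether an input library or an IP with weaker or no enrichment is the source stays open.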
